A study of Mus musculus with 9 samples.

How the data were processed

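Pancreatic islets, the clusters of endocrine cells that hold the insulin-secreting beta cells, were profiled by RNA sequencing in 9 mouse samples that fall into 3 groups of 3. Per the labels, islets came from untreated db/+ mice, from untreated db/db mice and from db/db mice that received imeglimin and metformin. Db/db mice carry a leptin receptor mutation on both chromosomes and become obese and diabetic, while db/+ mice carry it on 1 and serve as their control. Metformin and imeglimin are oral glucose-lowering drugs. Doses, duration, age and the number of mice behind a sample are not given in the sources used here, and no group received a single drug. The labels do not say that samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

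RNA was purified on columns and libraries were made with a kit that preserves strand, per the labels' protocols. Cutadapt 1.9.1, HISAT2 2.2.1, featureCounts 2.0.0 and genome build GRCm39 are named in the submitters' processing notes. The strand setting of the counting and the treatment of reads with several alignments are not given in the sources used here. The deposited values are raw counts per RefSeq transcript, per the file headers, for 139023 transcripts of 46316 gene symbols. Transcripts of a gene held nearly equal counts: the median ratio of the lowest to the highest was 0.96 over 7966 genes with several transcripts, so reads appear to have been counted in each transcript they overlap. Each gene was therefore represented by the transcript with the highest total over the 9 libraries, and adding transcripts up was run as an alternative. Genes that overlap another gene or its antisense partner are uncertain, as are members of families of near-identical genes (trypsinogens and other digestive enzymes, the insulin genes, immunoglobulin, Reg and MHC genes), whose reads can be split or lost. Genome coordinates are not printed because the annotation at hand is of build GRCm38, which was used only for GC content by gene symbol. Of the mitochondrial genome the table holds ribosomal RNAs but no protein genes, so the fixed list of those genes was not tested, nor was the adipocyte list, which had 1 tested member, Fabp4 (log2 fold change -1.25 between untreated db/db and db/+ islets).

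Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and, as an alternative, DESeq2 1.42.0; tables and figures were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Low genes were removed with edgeR's filterByExpr by group, which left 16811 genes tested and 29505 not tested. The main test was edgeR's quasi-likelihood F-test (TMM factors, robust fit) on the 9 libraries with 3 group means, no block and no covariate, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. All adjusted p-values for genes come from this test unless another is named. Fold changes are log2 values with standard errors; levels are TMM-normalised CPM (counts scaled to the library total), given as mean ± SD over 3 libraries. Where a whole group held 0 counts, the fold is a lower bound against 3 counts over the group; where it held 1 to 3 counts, the ratio is given with its exact 95% counting interval. Such intervals and bounds cover counting error only, because reads are not independent molecules.

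Gene totals ranged from 10292664 to 15281809 counts per library. In simulated data with the real libraries' means and sizes, 200 of 16811 genes were changed by known folds. At 1.5-fold, 2-fold and 4-fold the test recovered 23.9%, 55.2% and 87.9% of changed genes between untreated db/db and db/+ islets, 23.9%, 61.2% and 93.9% between treated and untreated db/db islets, and 41.8%, 53.7% and 89.4% between treated db/db and db/+ islets. Of its calls, 8.3%, 11.9% and 6.8% were false in these comparisons. The adjusted p depends on the share of genes changed, and 10620 and 10946 genes were called against db/+ islets in the data. These rates thus do not carry over to the comparisons with db/+ islets. The list test, also tested on simulated data, called the 1 list that was shifted and 0 of 33 that were not. Genes were drawn independently there, so it could not show how often lists of correlated genes are called falsely. In the data the lymphocyte and interferon lists had estimated correlations of 0.923 and 0.945.

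Sets of genes for islet cell types, other cells an islet preparation can hold, stress, metabolism, cell division and inflammation were fixed as 36 lists, of which 34 had at least 3 tested members. Each was tested with limma's camera, which compares a list's members with all other genes, at a preset correlation of 0.01 with adjustment over the lists of a comparison, and again with the correlation estimated for each list. Members passing the edgeR test were counted over all genes and adjusted over the list alone. The comparisons, lists, rule for named genes and most alternatives were fixed before the data were examined. The rule named, among called genes with a mean of at least 10 CPM in a group and no overlap between the groups' libraries, the 8 with the highest and the 8 with the lowest fold change (4 and 4 for treated db/db against db/+), leaving out predicted genes and pseudogenes. It added a panel of 20 islet genes, up to 4 members with the smallest p of each list described (all called members where 5 or fewer), and the 8 genes with the largest opposite changes. Values of some of these genes are not reported here; the genes stay in the tests, counts and lists.

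Alternatives were DESeq2, RLE and upper-quartile factors, no low count filter, a mean of at least 5 CPM, only the 2 groups compared, limma voom with quality weights, the replicate number as a block, a tested fold of at least 1.5, removal of acinar genes, the acinar score (mean log2 CPM of the list) as a covariate, and leaving out each library. Lists were also tested with fry, which tests a list's own members without comparing them with other genes. Chosen after seeing the data were other ways to combine transcripts, removal of islet hormone genes, and the lymphocyte score as a covariate. Replicate libraries were compared before averaging: every pair differed beyond sampling noise (chi-square per degree of freedom 9.93 to 47.9), and no library was left out of the main results.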

Results

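RNA of mouse pancreatic islets was sequenced in 3 samples from untreated db/+ mice, 3 from untreated db/db mice and 3 from db/db mice given imeglimin and metformin. Gene totals were 12403481, 10838426 and 10292664 counts in the db/+ libraries, 11711239, 15281809 and 13400670 in the untreated db/db libraries, and 14090744, 14677145 and 15135464 in the treated db/db libraries. The comparisons ask how islets of untreated db/db mice differ from those of db/+ mice, which genes differ with the combined treatment, and how treated db/db islets differ from db/+ islets. Errors on fold changes are standard errors, and group levels are means ± SD over 3 libraries each. Fold changes in parentheses without other words are log2 values of genes that passed the test unless a p above 0.05 is given. For the members of a list, counts adjusted over the list alone are given where they differ from those over all genes tested.

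The first principal component of log2 CPM held 69.9% of the variance and separated the db/+ libraries (-105.5 to -90.5) from the 6 db/db libraries (42.89 to 60.25). The second held 15.3% and placed the untreated db/db libraries (-68.22, -10.62 and -26.41) apart from the treated ones (29.89, 16.84 and 54.24), with untreated replicate 1 and treated replicate 3 farthest out. Markers of other cell types moved with the groups. The lymphocyte list averaged 4.333, 1.717 and 1.361 log2 CPM in the untreated db/db libraries, and from -1.721 to -1.011 in the other 6 libraries. Immunoglobulin and T cell receptor segments held 9577, 788 and 754 counts in the untreated db/db libraries, 11 to 16 in the db/+ libraries and 100 to 355 in the treated ones. The acinar list, digestive enzymes of the exocrine pancreas, averaged 6.232, 2.989 and 4.934 log2 CPM in the untreated db/db libraries, 2.84, 3.566 and 2.075 in the treated ones, and -0.1843, -1.052 and 2.161 in the db/+ libraries. Ddx3y, on the Y chromosome, held 1012 to 1206 counts per library and Xist 2 to 8, the pattern of male tissue in all 9 libraries. Lepr, the leptin receptor gene, held 7 to 29 counts per library (log2 fold change 0.53 ± 0.46, adjusted p = 0.334 in untreated db/db against db/+ islets); a count over the gene does not check the db mutation, which alters splicing.

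Islets of untreated db/db mice had lower levels of many genes of mature beta cells than db/+ islets. Mafa, a transcription factor of mature beta cells, fell from 536 ± 24.3 to 20.97 ± 8.13 CPM (log2 fold change -4.67 ± 0.45, adjusted p = 7.69e-05). Ucn3, a peptide that marks mature beta cells, fell from 326 ± 52.8 to 105 ± 21.5 CPM (log2 fold change -1.64 ± 0.16, adjusted p = 3.19e-06). Slc2a2, the beta cell glucose transporter GLUT2, fell from 127 ± 27.2 to 41.6 ± 17.3 CPM (log2 fold change -1.60 ± 0.35, adjusted p = 0.00532). The transcription factors Nkx6-1 and Pdx1 fell less, with log2 fold changes of -1.12 (adjusted p = 0.000953) and -0.81 (adjusted p = 6.22e-05). Ins1, an insulin gene, fell from 118205 ± 29700.2 to 32476 ± 15007 CPM (log2 fold change -1.86 ± 0.34, adjusted p = 0.000422), whereas Ins2 had a log2 fold change -0.64 ± 0.28, adjusted p = 0.0617. Iapp, the co-secreted islet amyloid polypeptide, rose (log2 fold change 1.35 ± 0.24, adjusted p = 0.000333). Of 23 beta cell genes tested, 14 fell and 3 rose. Among those with the smallest p were Gipr, the receptor for the incretin GIP (-2.97), the zinc transporter Slc30a8 (-2.68) and Isl1 (-1.24). The 3 that rose were Iapp, Ffar1, a fatty acid receptor (1.41), and Glp1r, the GLP-1 receptor (1.08), the last 2 named after their values were seen. The list had a camera adjusted p = 0.00293, and an adjusted p = 0.963 with an estimated correlation.

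The other genes lowest in untreated db/db islets by the naming rule included Trpm5, a cation channel of beta cells (log2 fold change -5.82 ± 0.36, adjusted p = 3.31e-06), and Kcnj12, a potassium channel, which went from 28.2 ± 1.06 to 0.298 ± 0.0774 CPM (log2 fold change -6.52 ± 0.33, adjusted p = 3.39e-08). Cox6a2, a cytochrome c oxidase subunit, had a log2 fold change -5.67 ± 0.52, adjusted p = 7.68e-05. T2 had a log2 fold change of -6.00, Fam151a -5.13, the activity-regulated transcription factor Npas4 -4.24 and the imprinted Nnat -4.08, with adjusted p from 1.59e-08 to 0.000129. Among hormones of other islet cells, Sst (somatostatin, delta cells) fell (log2 fold change -0.81 ± 0.22, adjusted p = 0.00744), while Gcg (glucagon, alpha cells) had a log2 fold change of 0.16 (adjusted p = 0.742) and Ppy of -0.40 (adjusted p = 0.0901). Of 22 genes of the secretory machinery, 10 fell and 7 rose, among them Sytl4, a granule docking protein (-2.42), and the granule proteins Chgb (2.44) and Scg2 (2.78); the list median was -0.12, its mean 0.080 and its camera adjusted p = 0.892.

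Most of the listed genes that mark dedifferentiated beta cells rose. Aldh1a3, an aldehyde dehydrogenase that marks failing beta cells, rose from 1.03 ± 0.697 to 172 ± 7.998 CPM (log2 fold change 7.37 ± 0.27, adjusted p = 9.56e-09). Gast, the hormone gastrin, which adult islets normally lack, rose to 48.2 ± 3.79 CPM (log2 fold change 6.77 ± 0.50, adjusted p = 8.22e-06). Cck, the hormone cholecystokinin, rose from 0.669 ± 0.127 to 291 ± 13.5 CPM (log2 fold change 8.75 ± 0.19, adjusted p = 2.37e-11). Of 13 dedifferentiation genes, 10 rose, among them Gc (3.43) and Aass (4.74), and 0 fell, as was also the case at an unadjusted p under 0.05, by DESeq2 and by voom. The list had a camera adjusted p = 0.00061, and an adjusted p = 0.134 with an estimated correlation. Vstm2a was detected with 1 count over the db/+ libraries and reached 25.9 ± 4.698 CPM in untreated db/db islets, a ratio with a counting interval of 140 to 30920. Of 21 genes that beta cells normally keep silent, 10 rose and 2 fell, with Cxcl12 at 2.74, Oat at 2.09 and Cat at 1.31; the camera adjusted p = 0.0821. The direction of this list turned with the acinar score as a covariate (adjusted p = 0.991). Bulk libraries do not show which cells hold these transcripts.

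Many genes of endoplasmic reticulum chaperones and of fatty acid oxidation were also higher in untreated db/db islets. Of 22 chaperone and unfolded protein response genes, 17 rose and 3 fell. These 3, named after their values were seen, were Dnajb11 (-0.36), Calr (-0.38) and Xbp1 (-0.30), and with upper-quartile factors 0 fell. Ern1, the stress sensor IRE1, rose by 1.62, Dnajc3 by 1.5, the disulfide isomerases Pdia6 and Pdia3 by 1.35 and 1.12, and Hspa5, the chaperone BiP, by 0.57 (adjusted p = 0.0228). The list had a camera adjusted p = 0.00293, and an adjusted p = 0.963 with an estimated correlation. Ddit3, the stress transcription factor CHOP, fell (log2 fold change -1.76 ± 0.13, adjusted p = 2.92e-07). Of 22 integrated stress response genes, 7 rose (6 adjusted over the list alone), among them Slc7a11 (2.10), and 5 fell (camera adjusted p = 0.892). Of 15 fatty acid oxidation genes, 8 rose, led by Cpt1a, which admits fatty acids to mitochondria (1.79), Etfdh (1.22), Hadhb (0.81) and Angptl4 (2.95), and 1 fell, Hadha (-0.32); the camera adjusted p = 0.0371, and the adjusted p = 0.963 with an estimated correlation. Txnip, a glucose-responsive inhibitor of thioredoxin, rose (log2 fold change 1.16 ± 0.10, adjusted p = 1.15e-06). Of 30 proliferation genes, 15 rose and 1 fell (14 and 0 adjusted over the list alone), among them Mcm4 (1.80), Mcm2 (1.07) and Rrm2 (2.05), while Mki67 had 0.74 (adjusted p = 0.0946); voom called 12 higher and 1 lower. The proliferation list had a camera adjusted p = 0.0371, and an adjusted p = 0.963 with an estimated correlation. It averaged 2.783, 1.961 and 1.933 log2 CPM in the untreated db/db libraries, highest in the library with the most lymphocyte counts. The group means differed by 0.727, or by 0.449 without that library, and with the lymphocyte score as a covariate the direction turned (adjusted p = 0.336).

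Respiratory chain genes moved both ways. Of 37 subunit genes of complex I, the mitochondrial NADH dehydrogenase, 9 rose and 15 fell, with a list median of -0.043 that turned to 0.065 with upper-quartile factors (camera adjusted p = 0.827). Of 29 genes of complexes II to V, 13 rose and 7 fell, with Atp5d at -1.56 and Cyc1 at -0.90 (camera adjusted p = 0.504). Of 12 genes of NAD metabolism, 6 rose and 3 fell (6 and 5 adjusted over the list alone). The list median of -0.051 turned to 0.056 with upper-quartile factors, its mean was 0.17, and camera gave an upward adjusted p = 0.892. Nampt, the enzyme that recycles nicotinamide to NAD, had a log2 fold change -0.48 ± 0.19, adjusted p = 0.051. Of 14 hypoxia genes, 9 rose and 1 fell, among them Pdk1, which restrains pyruvate oxidation (1.76), and Vegfa, which fell (-0.66; camera adjusted p = 0.062). Of 21 cholesterol synthesis and uptake genes, 13 rose and 6 fell, with Idi1 at 1.63 (camera adjusted p = 0.0981). Gdf15, a stress-induced hormone, had a log2 fold change of 0.50 (adjusted p = 0.14).

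Interferon-stimulated and endothelial genes were lower in untreated db/db islets. Of 15 interferon genes 12 fell and 0 rose, as was also the case at an unadjusted p under 0.05 and by DESeq2, while by voom 15 fell and 0 rose. Usp18 fell by 1.78, Oasl2 by 2.74, Rsad2 by 2.62 and Bst2 by 1.81 on the log2 scale. The list averaged 7.714, 7.84 and 7.781 log2 CPM in the db/+ libraries and 6.063, 4.798 and 5.908 in the untreated db/db libraries. Its camera adjusted p = 0.00199, and its adjusted p = 0.963 with an estimated correlation. Of 13 endothelial genes, 10 fell, among them Egfl7 (-1.72), Esam (-0.80) and the receptor Tie1 (-0.80), and 1 rose, Vwf, the clotting factor carrier (2.82); the camera adjusted p = 0.0371, and the adjusted p = 0.963 with an estimated correlation.

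**Figure D1:**
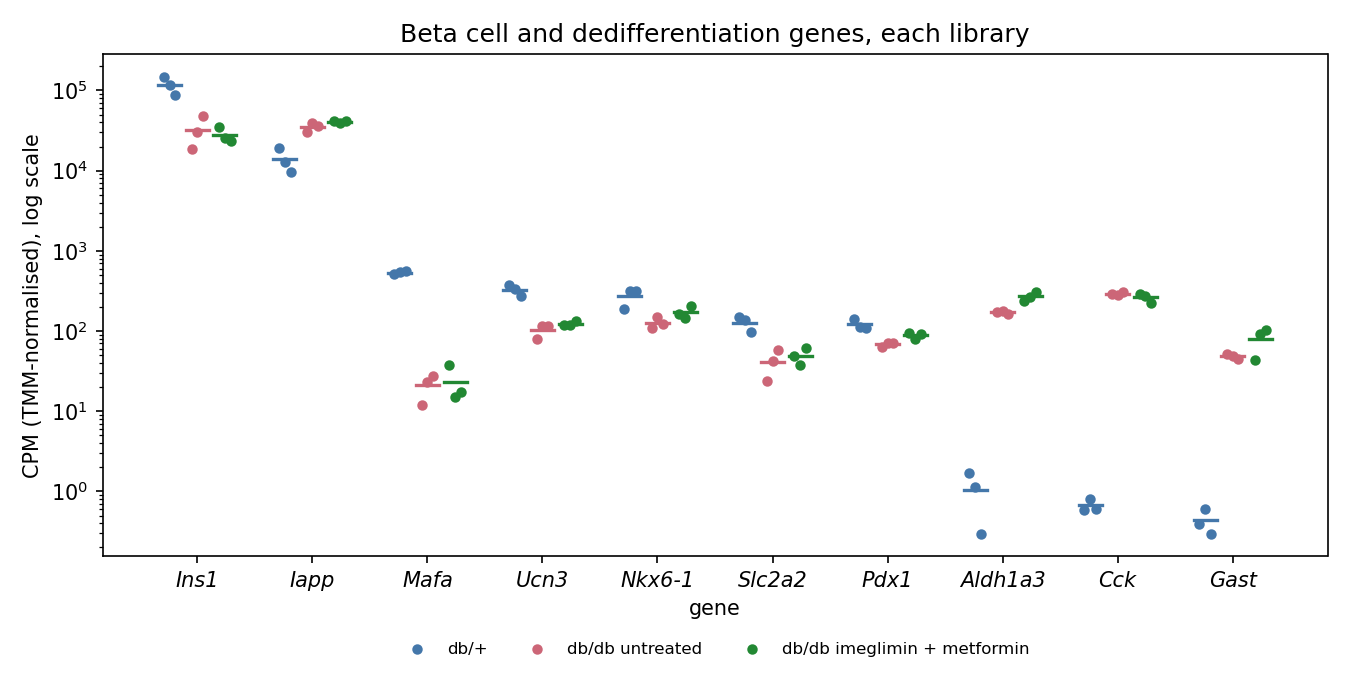
Expression of beta cell and dedifferentiation genes in each library, as TMM-normalised CPM on a log axis for 10 genes along the horizontal axis; points are libraries, bars are group means of 3. Mafa lay at 536 ± 24.3 CPM in db/+, 20.97 ± 8.13 in untreated db/db and 23.3 ± 12.3 in treated db/db islets, while Aldh1a3 lay at 1.03 ± 0.697, 172 ± 7.998 and 271 ± 36.00.

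Many genes of lymphocytes and of the exocrine pancreas were higher in untreated db/db islets. Ccl21a, a chemokine of lymphatic tissue, was at least 957-fold higher, with 0 counts in db/+ and 96.7 ± 47.5 CPM in untreated db/db islets (adjusted p = 0.000731). Glycam1, a ligand that lets lymphocytes enter lymph nodes from high endothelial venules, rose to 294 ± 126 CPM (log2 fold change 11.01 ± 0.70, adjusted p = 7.31e-06). The B cell gene Ms4a1 was at least 174-fold higher (adjusted p = 0.0479), and Igha, an immunoglobulin heavy chain, had 1 count in db/+ islets and a ratio with a counting interval of 174 to 38332 (adjusted p = 0.035). Of 12 lymphocyte genes, 9 rose and 0 fell, as was also the case at an unadjusted p under 0.05, by DESeq2 and by voom. The T cell genes Cd4 and Cd2 had 2 counts each in db/+ islets and rose with ratios of 86.3 (counting interval 23.6 to 716) and 93.5 (25.6 to 776). Cd3e had 1 count (28.3 to 6325), and Cd3d was at least 39.9-fold higher. Untreated db/db replicate 1 held much of the level of several of these genes: over the 3 untreated db/db libraries Ms4a1 lay at 48.6, 4.35 and 1.78 CPM and Igha at 96.1, 2.14 and 4.41. Without that library Ms4a1 was at least 31.38-fold and Cd3d at least 15.69-fold higher, and the counting intervals were 16.85 to 3836 for Igha, 11.01 to 344.7 for Cd2 and 11.28 to 2610 for Cd3e. The list median was 6.73, or 5.79 with the 4 genes of an empty group at their bound. Of 24 acinar genes, 18 rose and 1 fell, Amy1 (-1.49), while DESeq2 called 19 higher and voom 8. The trypsinogen Try5 rose by 6.97, and the lipase Pnliprp2 by 5.47. Prss1 had 2 counts in db/+ islets (interval of the ratio 290 to 8653), and Prss3 was at least 911-fold higher; without untreated db/db replicate 1 these were 122.9 to 3681 and at least 544.5-fold, with Try5 at 6.32 and Pnliprp2 at 4.74. Both lists had a camera adjusted p = 0.0371, and an adjusted p = 0.963 with an estimated correlation. Of 21 macrophage and MHC class II genes, 10 rose and 2 fell (9 and 2 adjusted over the list alone), with Lyz2 at 2.11 and C1qb at -0.58 (camera adjusted p = 0.195). Of 16 stellate and matrix genes, 10 rose and 1 fell, with fibronectin Fn1 at 4.77 and decorin Dcn at 3.55 (camera adjusted p = 0.0681).

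By edgeR's quasi-likelihood test 5260 of 16811 genes were higher and 5360 lower in untreated db/db than in db/+ islets at an adjusted p under 0.05, which is 63.2% of those tested. Of these, 2448 rose and 2387 fell at least 2-fold. The CPM of the 2 groups did not overlap in 67% of tested genes, against 10% on average over all splits of the libraries. Genes that move together can take a single split away from that average. The median log2 fold change of all genes was 0.024, and upper-quartile factors shifted gene values by a median of 0.107. Some calls were lost when 1 library was left out, which also leaves fewer samples to estimate the spread. The acinar list was lost without db/+ replicate 1 (adjusted p = 0.265), 2 (0.056) or 3 (0.106), with a range over all alternatives of 4.57e-05 to 0.978. The lymphocyte list was lost without db/+ replicate 1 (adjusted p = 0.163), 2 (0.056) or 3 (0.0784), with a range of 0.00158 to 0.963. The endothelial list was lost without db/+ replicate 1 (adjusted p = 0.077) or 2 (0.0554) or untreated db/db replicate 1 (0.0554) or 2 (0.0581), with a range of 0.00601 to 0.963. The fatty acid oxidation list was lost without db/+ replicate 2 (adjusted p = 0.0554; range 0.00105 to 0.963). The proliferation list was lost without db/+ replicate 1 (adjusted p = 0.109), 2 (0.0554) or 3 (0.0501) or untreated db/db replicate 1 (0.0967), with a range of 0.00558 to 0.978. Of named genes, Hspa5 was lost without db/+ replicate 2 (adjusted p = 0.0748) or 3 (0.0611) or untreated db/db replicate 3 (0.105), with a range of 0.00149 to 0.529. Sst was lost without db/+ replicate 3 (adjusted p = 0.051; range 0.000418 to 0.151) and Cd3d without treated replicate 2 (adjusted p = 0.0508; range 8.28e-05 to 0.0714). Igha was lost without db/+ replicate 1 (adjusted p = 0.0913), 2 (0.0893) or 3 (0.133) or treated replicate 1 (0.055), with a range of 0.00699 to 0.768. Ms4a1 was lost without db/+ replicate 1 (adjusted p = 0.0776), 2 (0.0746) or 3 (0.0815), untreated db/db replicate 2 (0.057), or treated replicate 1 (0.0919), 2 (0.0881) or 3 (0.0894), with a range of 2.21e-05 to 0.4. With the acinar score as a covariate the beta cell (adjusted p = 0.087), lymphocyte (0.546), endothelial (0.0996), fatty acid oxidation (0.0514) and proliferation (0.978) lists were lost, and the acinar list turned (0.978). With the lymphocyte score, chosen after seeing the data, the beta cell (adjusted p = 0.129), acinar (0.701), lymphocyte (0.369) and endothelial (0.336) lists were lost. Each score is the mean of its own list, so the results of the acinar and lymphocyte lists under their own scores are no separate checks. By fry the acinar (adjusted p = 0.265), lymphocyte (0.16) and proliferation (0.16) lists were lost.

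Other results passed when a library was left out, here with the adjusted p without it and the range over all alternatives. Nampt passed without untreated db/db replicate 1 (0.0108) or treated replicate 1 (0.0377) or 3 (0.02; range 0.0108 to 0.729), and Ins2 without db/+ replicate 3 (0.0133; range 0.00444 to 0.858). Mki67 passed without untreated db/db replicate 2 (0.0363) or 3 (0.0272; range 0.0123 to 0.599), and Ppy without untreated db/db replicate 2 (0.0429; range 0.0306 to 0.871). The low end for Mki67 came with the lymphocyte score as a covariate and in the opposite direction (log2 fold change -1.21). The hypoxia list passed without untreated db/db replicate 2 (0.0294) or treated replicate 1 (0.0301), 2 (0.0494) or 3 (0.039; range 0.0294 to 0.963). The matrix list passed without untreated db/db replicate 2 (0.00558) or treated replicate 2 (0.0361) or 3 (0.039; range 0.00558 to 0.963). The list of genes silent in beta cells passed without untreated db/db replicate 2 (0.0106) or treated replicate 3 (0.0462; range 0.0106 to 0.991). The macrophage list passed without untreated db/db replicate 2 (0.0294; range 0.0294 to 0.978), and complexes II to V without db/+ replicate 1 (0.0358; range 0.0358 to 0.963).

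In db/db islets, imeglimin with metformin went with lower levels of several T cell genes and of Glycam1, while beta cell genes of the panel did not pass the test. For lymphocyte and venule genes, a treatment effect cannot be told apart from lymph node tissue carried over with the untreated islets. Glycam1 fell from 294 ± 126 CPM in untreated to 1 count over the treated libraries (adjusted p = 0.00248; counting interval of the ratio 1.89e-06 to 0.000417). The T cell genes Cd4 (log2 fold change -5.35 ± 0.68, adjusted p = 0.00937), Foxp3, the transcription factor of regulatory T cells (-3.91), and Il2ra, the interleukin-2 receptor alpha chain (-3.99), fell as well, the last 2 named after their values were seen. Ubd, a ubiquitin-like protein induced by cytokines, fell (log2 fold change -7.35 ± 0.70, adjusted p = 0.0104), as did Csf2rb2 (log2 fold change -2.63 ± 0.30, adjusted p = 0.00937), a receptor subunit for interleukin-3. Lipg, endothelial lipase, fell from 12.4 ± 7.005 to 0.156 ± 0.0993 CPM (log2 fold change -6.22 ± 0.57, adjusted p = 0.00226). Serpina1e, an antitrypsin gene of a family of near-identical genes, fell from 10.004 ± 3.77 to 0.262 ± 0.169 CPM (log2 fold change -5.19 ± 0.49, adjusted p = 0.00226). Lrg1 fell from 19.6 ± 6.001 to 3.74 ± 1.29 CPM (log2 fold change -2.38 ± 0.26, adjusted p = 0.00319). The matrix protein gene Ltbp2 fell from 12.8 ± 3.898 to 2.94 ± 0.381 CPM (log2 fold change -2.11 ± 0.24, adjusted p = 0.00322), and Pdlim1 from 23.5 ± 4.09 to 7.05 ± 1.78 CPM (log2 fold change -1.74 ± 0.19, adjusted p = 0.00248). Rps6ka2, a ribosomal S6 kinase, was the 1 gene that rose, from 79.1 ± 4.46 to 110.2 ± 6.22 CPM (log2 fold change 0.48 ± 0.084, adjusted p = 0.0462).

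**Figure D2:**
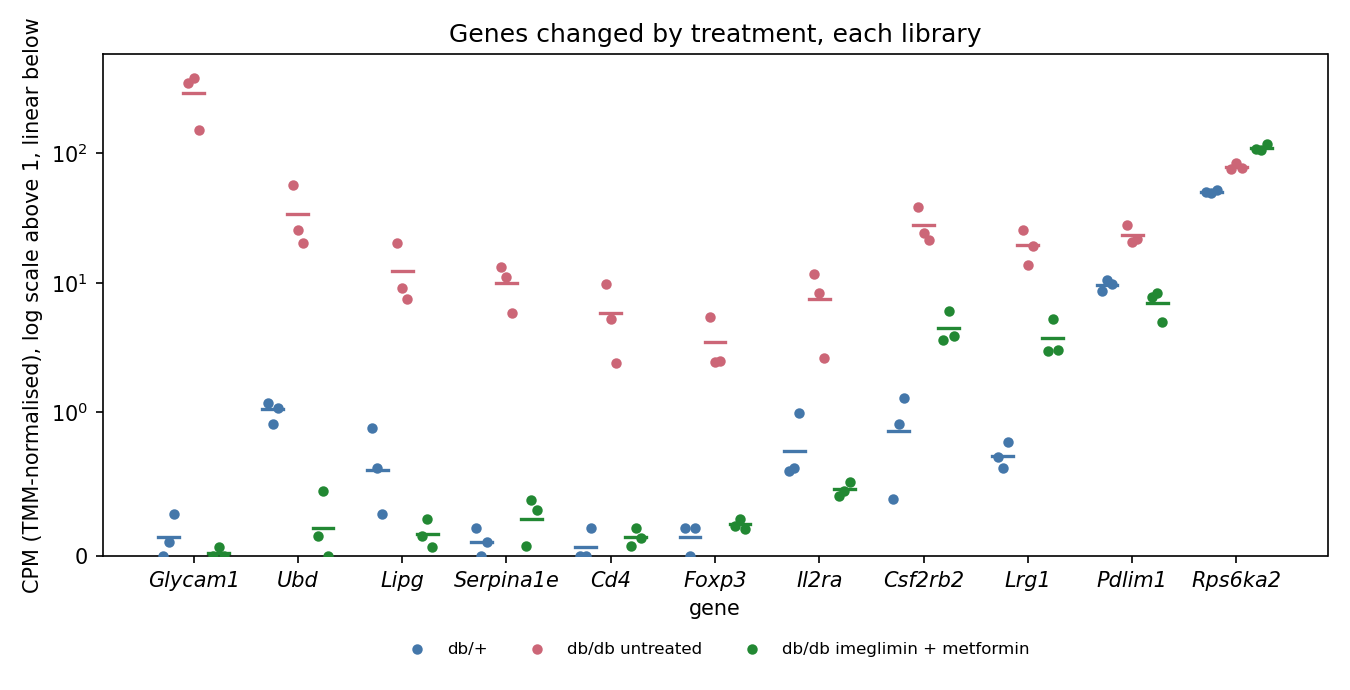
Expression of 11 genes that passed the treatment test in each library, as TMM-normalised CPM on an axis that is logarithmic above 1 and linear below; points are libraries, bars are group means of 3. Glycam1 lay at 294 ± 126 CPM in untreated db/db islets and at 0.0218 in treated ones, and Rps6ka2 is the 1 gene shown that was higher with treatment.

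Between treated and untreated db/db islets no beta cell gene of the panel passed the test. Mafa had a log2 fold change 0.15 ± 0.41, adjusted p = 0.875 and lay at 23.3 ± 12.3 CPM. Ins1 had a log2 fold change of -0.22 (adjusted p = 0.754) and Ins2 0.13 (adjusted p = 0.831). Pdx1 had 0.36 (adjusted p = 0.155), Nkx6-1 0.45 (adjusted p = 0.298) and Slc2a2 0.25 (adjusted p = 0.734). Ucn3 had 0.24 (adjusted p = 0.447) and Iapp 0.20 (adjusted p = 0.673). The dedifferentiation marker Aldh1a3 had a log2 fold change 0.65 ± 0.16, adjusted p = 0.0996 and Gast 0.71 (adjusted p = 0.248). Gcg and Sst had -0.82 and -0.52 (adjusted p = 0.323 and 0.257). Of the 23 beta cell genes 0 passed edgeR's test, over all genes or adjusted over the list alone, with 6 higher at an unadjusted p under 0.05 and 1 higher by DESeq2 and 1 by voom. The list had a median log2 fold change of 0.23, against 0.0705 over all genes tested, with Rfx6 at 0.47 (adjusted p = 0.105). Set against all other genes it was shifted up (camera adjusted p = 0.0036; adjusted p = 0.562 with an estimated correlation). The group means of the list differed by 0.235 log2 CPM, or by 0.096 without untreated db/db replicate 1. In the secretory machinery list 4 of 22 were higher adjusted over the list alone, Rims2 (0.43), Cacna1d (0.42), Chgb (0.55) and Scg5 (0.55). Over all genes 0 passed, with 6 higher at an unadjusted p under 0.05, 2 by DESeq2 and 0 by voom. Its camera adjusted p = 0.00106, and its adjusted p = 0.562 with an estimated correlation.

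Metformin inhibits complex I, and both drugs are known to act on mitochondria. Of the 37 complex I genes, 0 passed edgeR's test, with 1 higher at an unadjusted p under 0.05 and 0 by DESeq2 and voom. The list median was 0.10, the camera adjusted p = 0.299, and Ndufb4 and Ndufv2 had 0.26 and 0.21. Of the 29 genes of complexes II to V, 0 passed, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 and voom (camera adjusted p = 0.436). NAD metabolism had a camera adjusted p = 0.894, with Nampt at -0.19 (adjusted p = 0.625). Complex I (camera adjusted p = 0.0159) and NAD metabolism (0.0463) turned direction and were called with the lymphocyte score as a covariate, chosen after seeing the data. That score did not overlap between the groups, so these calls do not show an opposite treatment effect. Fatty acid oxidation had a camera adjusted p = 0.356, with 1 gene higher, Cpt1a (0.35), and 1 lower, Angptl4 (-1.26), adjusted over the list alone. Endoplasmic reticulum chaperones had a median of 0.16 and 0 of 22 members past the test, with 1 higher at an unadjusted p under 0.05 and 0 by DESeq2 and voom (camera adjusted p = 0.038; adjusted p = 0.802 with an estimated correlation). The group means of the chaperone list differed by 0.174 log2 CPM, or by 0.114 without untreated db/db replicate 1. Hspa5 had 0.20 (adjusted p = 0.609), Ddit3 0.28 (adjusted p = 0.27), Txnip 0.13 (adjusted p = 0.514) and Gdf15 -0.0049 (adjusted p = 0.994).

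Lists of immune and exocrine cells were lower in treated than in untreated db/db islets by camera, although few members passed edgeR's test one by one. Of 12 lymphocyte genes, 1 fell over all genes, Cd4, and 12 adjusted over the list alone, with 8 lower by DESeq2 and 5 by voom and a list median of -6.01, or -5.47 with the 2 genes of an empty group at their bound. Cd3e had 2 counts in treated islets (counting interval of the ratio 0.00101 to 0.0305; adjusted p = 0.0581) and Cd2 a log2 fold change of -3.69 (adjusted p = 0.0874). The list had a camera adjusted p = 7.84e-11, and an adjusted p = 0.487 with an estimated correlation. Of 21 macrophage and MHC class II genes, 0 passed over all genes and 11 were lower adjusted over the list alone, with 12 lower at an unadjusted p under 0.05, 9 by DESeq2 and 1 by voom. Lyz2 had a log2 fold change of -1.17, Cd68 -0.62 and Ptprc, the leukocyte antigen CD45, -3.85 (camera adjusted p = 4.53e-09; adjusted p = 0.487 with an estimated correlation). Of 24 acinar genes, 0 passed, over all genes or the list alone, with 8 lower at an unadjusted p under 0.05, 1 by DESeq2 and 0 by voom. Ctrl and Prss1 had -3.39 and -2.92 (camera adjusted p = 7.84e-11; adjusted p = 0.562 with an estimated correlation). Over the libraries, Prss1 lay at 157.8, 8.88 and 53.2 CPM in untreated and at 9.88, 12.6 and 6.52 CPM in treated db/db islets. The group means of the acinar list differed by -1.89 log2 CPM, or by -1.13 without untreated db/db replicate 1. Of the genes normally silent in beta cells, 0 of 21 passed over all genes and 7 were lower adjusted over the list alone, among them Tgm2 (-1.50) and Cxcl12 (-0.91). There were 11 lower at an unadjusted p under 0.05, 4 by DESeq2 and 1 by voom (camera adjusted p = 1.22e-09; adjusted p = 0.487 with an estimated correlation). Of 16 matrix genes 1 fell, Fn1 (log2 fold change -1.51 ± 0.24, adjusted p = 0.0452), and 2 were lower adjusted over the list alone (camera adjusted p = 6.42e-06; adjusted p = 0.562 with an estimated correlation). The group means of the matrix list differed by -0.717 log2 CPM, or by -0.43 without untreated db/db replicate 3.

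By edgeR's quasi-likelihood test 1 of 16811 genes was higher and 30 lower with treatment, which is 0.184% of those tested, with 2933 at an unadjusted p under 0.05. DESeq2 called 135 higher and 504 lower and voom 70 higher and 104 lower, and these included 31 and 28 of the 31. The CPM of the 2 groups did not overlap in 27.6% of tested genes, against 10% on average over all splits of the libraries. Because genes that move together can take a single split away from that average, this share does not show a broad treatment effect. The list calls of camera hold less weight than the gene calls: splitting the 6 db/db samples into other groups of 3 gave up to 19 lists against 17 for the real groups. Aldh1a3 passed by DESeq2 (adjusted p = 8.67e-05) and by voom (adjusted p = 0.0371), against a range over all alternatives of 8.67e-05 to 1. Of the 31 genes, 6 passed whichever library was left out (Glycam1, Lipg, Serpina1e, Lrg1, Ltbp2 and Pdlim1), and 25 were lost without at least 1 library, with adjusted p of up to 0.257. The number called was 13, 12 and 22 without db/+ replicate 1, 2 or 3, 154, 438 and 202 without untreated db/db replicate 1, 2 or 3, and 7, 38 and 6 without treated replicate 1, 2 or 3. The beta cell list was lost without untreated db/db replicate 1 (adjusted p = 0.146; range over all alternatives 5.84e-05 to 0.562). The chaperone list was lost without that library (adjusted p = 0.205), without untreated db/db replicate 2 (0.098) or without treated replicate 1 (0.194), with a range of 0.00179 to 0.802. When edgeR was fitted to the libraries of these 2 groups alone 0 genes were called, with 2803 at an unadjusted p under 0.05. With the lymphocyte score as a covariate, an alternative chosen after seeing the data, 1 gene was called. The beta cell (adjusted p = 0.00171), chaperone (0.0159), acinar (1.06e-05) and proliferation (5.47e-16) lists were then called in the opposite direction. The lymphocyte list averaged 4.333, 1.717 and 1.361 log2 CPM in untreated and -1.721, -1.011 and -1.695 in treated db/db libraries, without overlap. The score thus takes up much of the group difference, and these calls do not show an opposite treatment effect. That score also ended the calls of the secretory machinery (adjusted p = 0.179), macrophage (0.224) and alpha cell (0.323) lists and of genes silent in beta cells (0.441). The acinar score as a covariate ended those of the beta cell (adjusted p = 0.216), secretory machinery (0.0904), chaperone (0.705), matrix (0.0801) and acinar (0.616) lists. The last is no separate check, because that score is the mean of the acinar list. By fry 0 of the 17 lists were called (adjusted p of 0.249 or more).

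Among genes that missed the treatment test, Gast passed without treated replicate 1 (adjusted p = 0.0196; range over all alternatives 0.0196 to 1). Lyz2 passed without untreated db/db replicate 1 (adjusted p = 0.00708) or 2 (0.0177; range 0.000222 to 0.999), and Ptprc without untreated db/db replicate 1 (adjusted p = 0.00427; range 0.000239 to 0.999). Without untreated db/db replicate 2 the adjusted p was 0.0318 for Tgm2 (range 8.52e-07 to 0.999), 0.0427 for Ctrl (range 0.00651 to 0.999) and 0.0404 for Prss1 (range 0.0404 to 0.999).

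Treated db/db islets differed from db/+ islets in most genes tested. Aldh1a3 lay at 271 ± 36.00 CPM (log2 fold change 8.02 ± 0.27, adjusted p = 5.21e-09) and Cck at 265 ± 34.3 CPM (log2 fold change 8.62 ± 0.18, adjusted p = 2.83e-11). Csn3, a casein gene, had 3 counts in db/+ islets and a ratio with a counting interval of 147 to 2082, and Vstm2a 1 count and an interval of 191 to 42177. Lowest were Kcnj12 (log2 fold change -6.11 ± 0.32, adjusted p = 2.43e-08), Cox6a2 (-5.98), Trpm5 (-5.80) and T2 (-5.44). Mafa (log2 fold change -4.53 ± 0.45, adjusted p = 7.45e-05), Ins1 (log2 fold change -2.08 ± 0.34, adjusted p = 0.000167) and Ucn3 (-1.40) fell. Slc2a2 (-1.35, adjusted p = 0.0105), Pdx1 (-0.45, adjusted p = 0.00414) and Nkx6-1 (-0.67, adjusted p = 0.0158) also fell, and Iapp rose (log2 fold change 1.56 ± 0.24, adjusted p = 9.84e-05). Nampt fell (log2 fold change -0.67 ± 0.19, adjusted p = 0.0113), as did Ddit3 (-1.48) and Sst (-1.33), while Gast (7.47), Txnip (1.29) and Hspa5 (0.77) rose.

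Of 23 beta cell genes, 13 fell and 4 rose in treated db/db against db/+ islets (camera adjusted p = 0.0425; adjusted p = 1 with an estimated correlation). Of 13 dedifferentiation genes 9 rose (camera adjusted p = 0.00467; adjusted p = 0.328 with an estimated correlation). Of 22 chaperone genes 17 rose and 1 fell, Dnajb11 (-0.31; camera adjusted p = 0.00157), and of 15 fatty acid oxidation genes 9 rose (camera adjusted p = 0.034). Both lists had an adjusted p = 1 with an estimated correlation. Of 13 endothelial genes 11 fell, among them Eng (-1.60), and 1 rose, Vwf (2.02; camera adjusted p = 0.0153; adjusted p = 1 with an estimated correlation). All 15 interferon genes fell (camera adjusted p = 0.000279; adjusted p = 1 with an estimated correlation), and the list averaged 5.371, 5.393 and 3.26 log2 CPM in the treated libraries. Immunoglobulin and T cell receptor segments held 100, 153 and 355 counts in the treated libraries and 16, 12 and 11 in the db/+ libraries. The lymphocyte list was not called. Its genes averaged only -1.721 to -1.011 log2 CPM in these libraries, too low to show that the groups are alike. Of 12, 1 fell, Cd79a (-4.35), and 0 adjusted over the list alone, with 1 lower at an unadjusted p under 0.05, 0 lower and 1 higher by DESeq2, and 1 lower by voom. The list median was 0.17, or 0.0070 with 4 genes of an empty group at their bound, with a mean of 0.47 and a downward camera adjusted p = 0.99. Of 24 acinar genes 3 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.507), with 6 higher at an unadjusted p under 0.05, 8 higher and 2 lower by DESeq2, and 2 and 2 by voom.

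The edgeR test called 5495 genes higher and 5451 lower in treated db/db than in db/+ islets, 65.1% of those tested. Of these, 2633 rose and 2696 fell at least 2-fold. The CPM of the 2 groups did not overlap in 70.8% of tested genes, against 10% on average over all splits of the libraries. Nkx6-1 was lost without db/+ replicate 3 (adjusted p = 0.0582) or treated replicate 1 (0.0531) or 2 (0.0588), with a range over all alternatives of 0.000432 to 0.305. Nampt was lost without db/+ replicate 1 (adjusted p = 0.081; range 0.00124 to 0.29). The beta cell list was lost without db/+ replicate 1 (adjusted p = 0.057) or 2 (0.0564), with a range of 0.00414 to 1, and the fatty acid oxidation list without db/+ replicate 2 (adjusted p = 0.0502; range 0.000235 to 1). The beta cell list was also lost with the acinar score as a covariate (adjusted p = 0.156).

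**Figure D3:**
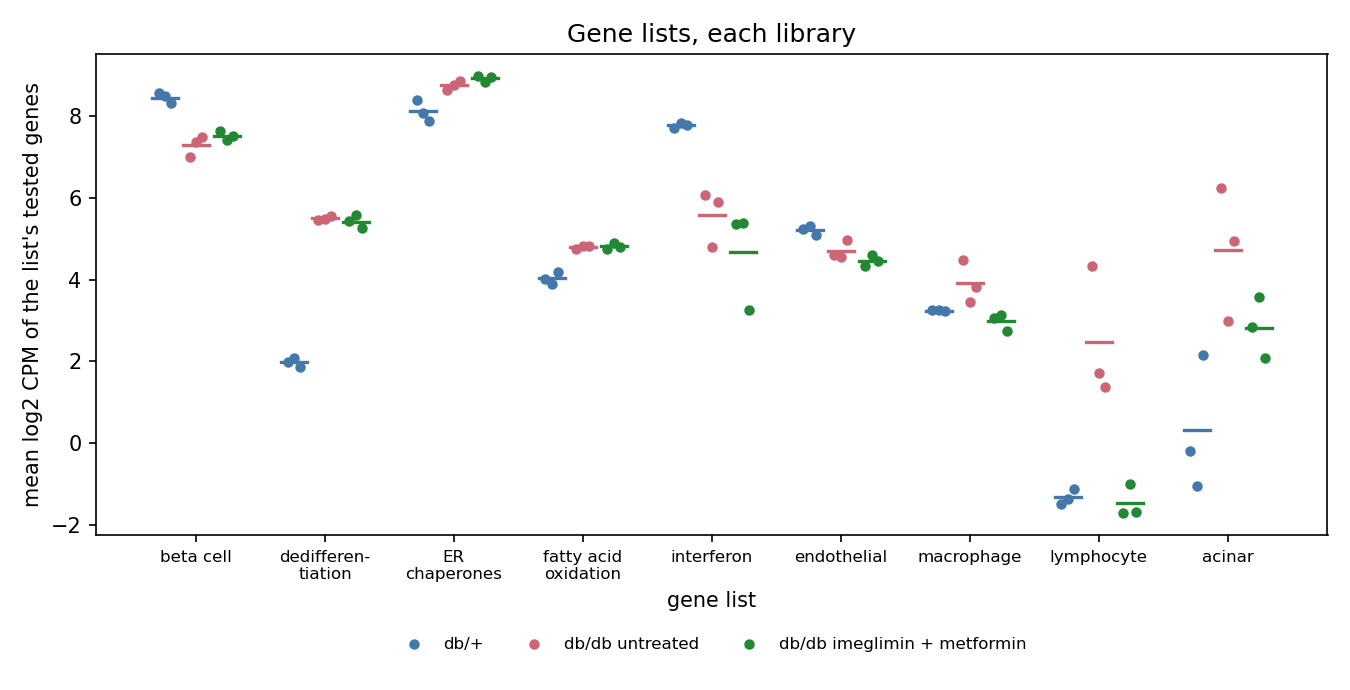
Mean log2 CPM of the tested genes of 9 lists in each library, lists along the horizontal axis; points are libraries, bars are group means of 3. The lymphocyte list lay at 4.333, 1.717 and 1.361 in untreated db/db libraries and between -1.721 and -1.011 in all others, while the beta cell list lay at 8.318 to 8.558 in db/+ libraries and at 7.01 to 7.626 in the 6 db/db libraries.

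Genes higher in untreated db/db than in db/+ islets and lower with treatment numbered 26, and 0 were lower in untreated db/db islets and higher with treatment by edgeR. At an unadjusted p under 0.05 these were 518 and 340, by DESeq2 293 and 21, and by voom 81 and 6. Those with the largest opposite changes were Glycam1, Pdcd1, the T cell checkpoint receptor PD-1 (at least 62.1-fold higher in untreated db/db than db/+, then 2 counts with treatment, interval of the ratio 0.000862 to 0.0261), and Chst4, a sulfotransferase of high endothelial venules (at least 21.3-fold, then 1 count, 0.000261 to 0.0596). The others were Tnfsf11, the cytokine RANKL (interval of the ratio 14.4 to 3257, then 2 counts, 0.00195 to 0.0602), Cd4, Serpina1e (interval 34.0 to 487, then a log2 fold change of -5.19), Spn, a leukocyte surface protein (interval 13.1 to 191, then -5.04, or -4.18 without untreated db/db replicate 1), and Ubd (4.99, then -7.35). Both changes share the untreated db/db libraries, which alone gives opposite changes. Lymph node tissue carried over with the untreated db/db islets would also give opposite changes of venule and lymphocyte genes, and cannot be told apart here. Independent lists of these sizes would share 9.39 genes, and 20 simulations that kept the change from db/+ to db/db islets, with no treatment effect, gave a mean of 0.5 and at most 2 opposite genes. Those simulations drew each gene independently. They do not cover genes that move together, as the lymphocyte list did (estimated correlation 0.923). The same direction in both changes was seen for 1 gene higher and 3 lower. The count was 13 and 11 without db/+ replicate 1 or 2, 127, 264 and 174 without untreated db/db replicate 1, 2 or 3, and 6 and 6 without treated replicate 1 or 3. Of the genes changed between untreated db/db and db/+ islets, 4617 were also higher and 4806 also lower in treated db/db than in db/+ islets (1720 and 1740 for independent lists, though both share the db/+ libraries), and 4 and 0 went the opposite way.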

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

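Alternatives chosen after seeing the data were the highest transcript in each library, the sum over transcripts, removal of hormone genes and the lymphocyte score as a covariate. The 139 gene values that passed the test kept direction under each alternative that gave them a value (their side of the threshold was kept in 2960 cases and lost in 333). Many of these genes were named for large changes without overlap in the same data, so a kept direction was likely and is weak evidence. Gene values that had not passed kept direction and side in 1898 cases, passed in 70 and reversed in 63. List calls kept direction and side in 329 cases, were lost in 104 and reversed in 15, and lists not called stayed so in 851 cases, were called in 44 and reversed in 85. The counts of genes between each db/db group and db/+ islets stayed within 1.5 times of the main count under all alternatives but those named here. Asking for a fold of at least 1.5 gave 2615 higher and 2786 lower in untreated db/db and 2975 and 3023 in treated db/db islets. For untreated db/db islets the lymphocyte score as a covariate gave 2820 higher and 2637 lower, and the acinar score 3490 lower. A fold floor makes a stricter test, and a score that differs between the groups takes their difference into the covariate; the other causes were not tested.

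Among the counts of genes, the treatment counts of 1 higher and 30 lower and the 26 opposite genes changed most. DESeq2 gave 135 higher, 504 lower and 314 opposite; voom gave 70, 104 and 87; no low count filter gave 12, 215 and 135. A mean CPM of at least 5 gave 0, 9 and 7, only the 2 groups compared 0, 0 and 0, and the sum over transcripts 0, 9 and 9. The acinar score as a covariate gave 0, 11 and 8, and the lymphocyte score 0, 1 and 1. A tested fold of at least 1.5 gave 0 higher and 18 lower, and RLE and upper-quartile factors gave 0 and 0 higher. The replicate block gave 126 lower and 112 opposite genes, but the numbers do not pair the samples: same-numbered libraries of different groups had residual correlations of -0.425 to 0.0568. With 1 library left out the treatment counts ran from 0 to 67 higher, 6 to 371 lower and 6 to 264 opposite. Called lists numbered 9, 17 and 6 for untreated db/db against db/+, treatment, and treated db/db against db/+. With an estimated correlation 0, 0 and 0 were called. The acinar score as a covariate gave 3 and 7 for the first 2 of these, and fry gave 0 for treatment and 10 for treated db/db against db/+. With 1 library left out the first ran from 4 to 13 and the last from 4 to 10.

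Results reversed 163 times, of which 98 under the 2 covariates and 53 with a library left out, and 4 of them passed the threshold both ways. With the lymphocyte score as a covariate the reversed adjusted p of lists for untreated db/db against db/+ were secretory machinery 0.488, macrophage 0.376, erythroid 0.578, complex I 0.496, citric acid cycle 0.703, NAD metabolism 0.941 and proliferation 0.336. Under the lymphocyte score as a covariate the reversed log2 values of genes for untreated db/db against db/+ were Ins2 0.16, Gcg -0.85 and Mki67 -1.21. With the lymphocyte score as a covariate the reversed adjusted p of lists for treated against untreated db/db were beta cell 0.00171, secretory machinery 0.179, delta and PP cell 0.683, acinar 1.06e-05, Reg family 0.441, macrophage 0.224, chaperone 0.0159, integrated stress 0.000703, complex I 0.0159, complexes II to V 0.0801, citric acid cycle 0.0779 and hypoxia 0.642. Under the lymphocyte score as a covariate the reversed adjusted p of lists for treated against untreated db/db were glucose-responsive 0.526, fatty acid oxidation 0.615, NAD metabolism 0.0463, proliferation 5.47e-16, inflammation 0.558, interferon 0.642, autophagy 0.0159 and ribosomal protein 0.00666. With the lymphocyte score as a covariate the reversed log2 values of genes for treated against untreated db/db were Lepr 0.03, Ins2 -0.68, Gcg 0.18, Iapp -0.30, Mafa -1.43, Slc2a2 -1.38, Ucn3 -0.53, Ddit3 -0.21, Hspa5 -0.15, Txnip -0.27, Mki67 1.68 and Nampt 0.37. Under the lymphocyte score as a covariate the reversed log2 values of genes for treated against untreated db/db were Nkx2-2 -0.072, Maf 0.002, Irx1 0.10, Ghrl 0.76, Ctrl 0.70, Prss1 0.22, Lyz2 0.17, Ptprc 0.36, Laptm5 0.70, Ern1 -0.14, Herpud1 -0.28 and Sel1l -0.18. With the lymphocyte score as a covariate the reversed log2 values of genes for treated against untreated db/db were Atf6 -0.17, Mcm6 0.25, Mcm3 0.93, Pcna 0.094, Mcm5 1.51, Cxcl1 0.57 and Usp18 0.12. Under the lymphocyte score as a covariate the reversed adjusted p of the list for treated db/db against db/+ was complex I 0.985. With the acinar score as a covariate the reversed adjusted p of lists for untreated db/db against db/+ were secretory machinery 0.546, genes silent in beta cells 0.991, acinar 0.978, ductal 0.605, macrophage 0.978, complex I 0.407, citric acid cycle 0.728 and glycolysis 0.978. Under the acinar score as a covariate the reversed log2 values of genes for untreated db/db against db/+ were Lepr -0.46, Ins2 0.12, Gcg -0.61 and Mki67 -0.39. With the acinar score as a covariate the reversed adjusted p of lists for treated against untreated db/db were acinar 0.616, integrated stress 0.545, complex I 0.209, complexes II to V 0.216, citric acid cycle 0.471, NAD metabolism 0.738, proliferation 0.305 and autophagy 0.603. Under the acinar score as a covariate the reversed log2 values of genes for treated against untreated db/db were Lepr 0.20, Ins2 -0.19, Iapp -0.075, Mafa -0.024, Slc2a2 -0.19, Ucn3 -0.015, Mki67 0.23, Nampt 0.032, Gdf15 0.095 and Reg2 0.063. With the acinar score as a covariate the reversed adjusted p of lists for treated db/db against db/+ were genes silent in beta cells 0.459, acinar 0.892, Reg family 0.982 and Schwann cell 0.993. Under the acinar score as a covariate the reversed log2 values of genes for treated db/db against db/+ were Lepr -0.27 and Mki67 -0.15. With fry the reversed adjusted p of lists for untreated db/db against db/+ were Schwann cell 0.807 and glycolysis 0.807. Under fry the reversed adjusted p of lists for treated against untreated db/db were dedifferentiation 0.904 and NAD metabolism 0.684. With fry the reversed adjusted p of lists for treated db/db against db/+ were Schwann cell 0.581, citric acid cycle 0.565 and p53 and senescence 0.882. Under voom the reversed log2 values of genes for treated against untreated db/db were Mafa -0.069 and Mki67 0.082. With the replicate block the reversed adjusted p of the list for untreated db/db against db/+ was p53 and senescence 0.951. Under the replicate block the reversed log2 value of the gene for treated against untreated db/db was Gdf15 0.017. With the replicate block the reversed adjusted p of the list for treated db/db against db/+ was complex I 0.999. With 1 library left out, results with a reversal ranged as follows. For untreated db/db against db/+, the list ranges were secretory machinery 0.725 to 0.996, ductal 0.631 to 0.996, erythroid 0.718 to 0.996, complex I 0.361 to 0.957, citric acid cycle 0.675 to 0.996, glycolysis 0.725 to 0.996, p53 and senescence 0.855 to 0.996, inflammation 0.412 to 0.923 and ribosomal protein 0.281 to 0.75. For treated against untreated db/db, the list ranges were dedifferentiation 0.314 to 0.97, erythroid 0.103 to 0.765, integrated stress 0.196 to 0.862, citric acid cycle 0.347 to 0.938, glycolysis 0.00128 to 0.828, hypoxia 0.00538 to 0.733, NAD metabolism 0.55 to 0.99, proliferation 0.00157 to 0.381 and ribosomal protein 0.0239 to 0.733. For treated against untreated db/db, the gene ranges were Lepr -0.61 to 0.049, Ins1 -0.49 to 0.19, Ins2 -0.034 to 0.24, Mafa -0.37 to 0.40, Slc2a2 -0.028 to 0.57, Mki67 -0.53 to 0.29 and Gdf15 -0.16 to 0.20. For treated db/db against db/+, the list ranges were genes silent in beta cells 0.612 to 0.989, lymphocyte 0.836 to 0.991, Schwann cell 0.88 to 0.994, erythroid 0.574 to 0.977, complex I 0.463 to 0.977, citric acid cycle 0.726 to 0.988, glycolysis 0.566 to 0.989, p53 and senescence 0.935 to 0.989 and ribosomal protein 0.262 to 0.989. For treated db/db against db/+, the gene ranges were Ppy -0.28 to 0.04. The causes of these reversals were not tested. Because the acinar score is the mean of the acinar list, that list's own reversals under it are no separate check. With these library sizes, spreads and numbers of samples, simulated 1.5-fold changes were recovered in 23.9% of cases in the treatment comparison, so an uncalled gene is not shown to be unchanged.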

Other observations

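Chosen after the result was seen were the tests of a single library, of non-islet cells and of lymph node tissue for the lymphocyte genes, of hormone genes for the number of changed genes, and of beta cell share; the GC and length correction and the splits of the samples were planned. Several other groups were shifted down in treated against untreated db/db islets by camera, with few members past edgeR's test. Of 17 inflammation genes 0 passed over all genes and 1 was lower adjusted over the list alone, the chemokine Cxcl9 (-3.09), with 3 lower at an unadjusted p under 0.05, 2 by DESeq2 and 0 by voom. The list had a camera adjusted p = 9.19e-07, and an adjusted p = 0.562 with an estimated correlation. The 15 interferon genes had a median of -0.68 and 0 passed, with 1 lower at an unadjusted p under 0.05 and 0 by DESeq2 and voom (camera adjusted p = 3.4e-06; adjusted p = 0.562 with an estimated correlation). Treated replicate 3, at 3.26 log2 CPM on average, lay below 5.371 and 5.393 in the other treated libraries. The inflammation list averaged 4.526, 4.571 and 2.3 log2 CPM in the treated libraries and 5.694, 4.414 and 5.099 in the untreated db/db libraries. Of 14 immediate early genes 0 passed over all genes and 3 were lower adjusted over the list alone, Ier2 (-0.61), Fos (-0.70) and Egr1 (-0.46), with 5 lower at an unadjusted p under 0.05, 2 by DESeq2 and 0 by voom. Ier2 had an adjusted p = 0.0379 without untreated db/db replicate 2 (range over all alternatives 0.0117 to 1). The list had a camera adjusted p = 3.97e-05, and an adjusted p = 0.487 with an estimated correlation. Without treated replicate 3 the difference of the group means went from -1.27 to -0.521 log2 CPM for the inflammation list, from -0.915 to -0.208 for interferon and from -0.381 to -0.207 for immediate early genes.

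The alpha cell list had a median of -0.66 with treatment and 0 of 8 past edgeR's test, with 2 lower at an unadjusted p under 0.05 and 0 by DESeq2 and voom (camera adjusted p = 0.000209; adjusted p = 0.487 with an estimated correlation). All 3 tested genes of the Reg family, secreted proteins of injured pancreas, were lower adjusted over the list alone, Reg3b (-2.30), Reg1 (-2.64) and Reg2 (-3.65), and 0 over all genes, with 3 at an unadjusted p under 0.05 and 0 by DESeq2 and voom. This list had a camera adjusted p = 0.0164 (adjusted p = 0.562 with an estimated correlation) and was lost without db/+ replicate 1 (adjusted p = 0.0726; range over all alternatives 1.46e-06 to 0.562). Of 13 endothelial genes 2 were lower adjusted over the list alone, Pecam1 (-0.42) and Cdh5 (-0.39), and 0 over all genes, with 5 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by voom. This list had a camera adjusted p = 0.00376 (adjusted p = 0.562 with an estimated correlation) and was lost without untreated db/db replicate 3 (adjusted p = 0.278; range 1.73e-05 to 0.562). Ductal genes had a camera adjusted p = 0.0047 (adjusted p = 0.575 with an estimated correlation), lost without untreated db/db replicate 3 (adjusted p = 0.258; range 0.000166 to 0.575). Delta and PP cell genes had a camera adjusted p = 0.0101 (adjusted p = 0.562 with an estimated correlation), lost without untreated db/db replicate 2 (adjusted p = 0.0985) or treated replicate 1 (0.185; range 7.81e-05 to 0.683). Proliferation genes had a camera adjusted p = 0.0475 (adjusted p = 0.802 with an estimated correlation). That call was lost without db/+ replicate 1 (adjusted p = 0.148), 2 (0.125) or 3 (0.123) or treated replicate 1 (0.22) or 3 (0.0509), and the direction turned without untreated db/db replicate 1 (adjusted p = 0.381; range 5.47e-16 to 0.802). The low end of that range came with the lymphocyte score as a covariate and in the opposite direction. The group means of the endothelial list differed by -0.251 log2 CPM (-0.123 without untreated db/db replicate 3). Those of the ductal list differed by -0.462 (-0.237 without that library and -0.265 without treated replicate 3), and those of the delta and PP cell list by -0.391 (-0.627 without treated replicate 2). Those of the proliferation list differed by -0.129, or by 0.15, -0.261 and -0.275 without untreated db/db replicate 1, 2 or 3 and -0.0802 without treated replicate 1. With the acinar score as a covariate the Reg (adjusted p = 0.235), ductal (0.216), delta and PP cell (0.0982) and interferon (0.0666) lists were lost. The Reg (adjusted p = 0.441), delta and PP cell (0.683), inflammation (0.558) and interferon (0.642) lists turned direction, without a call, with the lymphocyte score as a covariate. Without untreated db/db replicate 2 the adjusted p was 0.0429 for Reg3b (range over all alternatives 0.0429 to 1), 0.0366 for Reg2 (range 0.0366 to 1) and 0.021 for Pecam1 (range 0.0174 to 1). Between untreated db/db and db/+ islets, Reg1 rose by 5.10 and Reg3b by 4.97, the 2 of 3 Reg genes past the test (camera adjusted p = 0.491; 0.0294 without untreated db/db replicate 2, range 0.0294 to 0.978). Of 14 immediate early genes 3 rose and 7 fell, with Btg2 at 1.15 and Nr4a1 at -0.74 (camera adjusted p = 0.507). Of 28 ribosomal protein genes 4 rose and 10 fell (2 and 9 adjusted over the list alone), with a median of -0.041 that turned to 0.068 with upper-quartile factors (camera adjusted p = 0.518).

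Lymphocyte genes were lower in treated than in untreated db/db islets, with a list median of -6.01. Over all genes 1 of 12 passed, and the list call was lost with an estimated correlation (adjusted p = 0.487) and by fry (0.249). A single library is not the whole cause. Without untreated db/db replicate 1, which held the most lymphocyte counts, the median was -4.722, or -4.318 with empty-group genes at their bound. The standard error of the members' mean was 0.577, taken over genes that move together and not over samples. A lower share of all non-islet cells in treated islets would move their lists alike only if all such cells changed by 1 common factor. The endothelial list averaged 5.244, 5.303 and 5.102 log2 CPM in db/+ libraries and 4.605, 4.558 and 4.967 in untreated db/db libraries. The lymphocyte list averaged -1.489, -1.376 and -1.132 in db/+ libraries, so a loss of lymphocyte-rich tissue need not lower both lists alike. The lymphocyte list differed in mean log2 change from the endothelial list by -5.625 (pooled SD 1.49). It differed by -3.572 (pooled SD 1.52) from the acinar list, which had a mean of -2.327. The pooled SD is over list members that move together and not over samples. These differences thus do not decide whether such a share is part of the cause or the whole. Of 24 acinar genes 0 passed, and that list was not called with an estimated correlation (adjusted p = 0.562) or by fry (0.413). Lymph node tissue carried over with the untreated islets stays open and cannot be told apart from the group: 4 of 5 venule markers reached 1 CPM in each untreated db/db library (Glycam1 at 349.8, 381.8 and 150.1 CPM), while the ratio of B cell to venule markers differed 10.04-fold between these libraries. Fewer lymphocytes in or around the islets of treated mice may be a biological explanation, which was not tested.

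In untreated db/db against db/+ islets 63.2% of tested genes changed. Trends with GC content and transcript length are not the main cause: after their removal in each library, 80.9% of the calls among matched genes stayed (7979 of 9863, with 92.6% of tested genes matched), although the correction moved fold changes by a median of 0.242. A different share of reads taken by hormone genes would shift all other genes by 1 common factor. Of these genes 69.4% lay more than 2 standard errors from their median log2 fold change of 0.0241, which 1 common factor does not account for. TMM factors had already taken out a common factor, so this count largely restates the gene calls and is no separate evidence. Differences in the mix of cell types between the groups stay open, as does the diabetic and obese state of db/db mice, which may act on many genes at once and was not tested apart from genotype. Ribosomal RNA held 0.424%, 0.649% and 0.962% of gene counts in the db/+ libraries and 0.142% to 0.212% in the db/db libraries. A difference between the libraries that coincides with genotype cannot be told apart from it.

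Beta cell genes were lower in untreated db/db than in db/+ islets. A lower share of beta cells would lower members made mostly in beta cells by about the same amount. Of all list members, 73.9% lay more than 2 standard errors from the list median of -0.8134, but members also made in other cells can add to this. Of 23 members 14 fell and 3 rose, among the last Iapp (1.35), which a lower share alone would not give. A lower share is thus not the whole cause, and part of the fall may still come from it. Loss of mature identity in the beta cells that remain, with higher Aldh1a3 and Gast, is a hypothesis that these bulk libraries do not test.

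Splits of 6 samples into 3 and 3 number 10, too few for a share under 0.05. For genes, the real split gave 10620 between untreated db/db and db/+ islets and the highest other 0, so 1 of 10 splits gave as many. With treatment these were 31 and 1 (1 of 10), for treated db/db against db/+ islets 10946 and 0 (1 of 10), and for opposite genes 26 and 1 (1 of 10). For lists called by camera the real split did not stand out. It gave 9 lists between untreated db/db and db/+ islets against up to 14 in the others (8 of 10 splits gave as many), 17 with treatment against 19 (4 of 10), and 6 for treated db/db against db/+ islets against 17 (10 of 10).

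Over all tested genes, the changes from db/+ to untreated db/db and from untreated to treated db/db islets had a covariance of -0.1268 and a correlation of -0.1993, and 44.51% of genes moved in opposite directions. Simulated data that kept the change from db/+ to db/db, with no treatment effect, gave -0.03819 (SD 0.00383 over 50 simulations), -0.1156 (SD 0.0111) and 53.3% (SD 0.362), since both changes share the untreated libraries. The covariance and correlation were thus more opposite than in the simulations and the share of genes was less so. The simulations drew genes independently, so their SD leaves out genes that move together. Without untreated db/db replicate 1 the 3 values were -0.0605, -0.1154 and 43.26%, and the spread of the remaining 2 untreated libraries alone gives a covariance of -0.04752. Genes are not independent replicates, and these measures do not agree on a general reversal.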
